A study of Homo sapiens with 8 samples.

How the data were processed

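The series holds 8 arrays of human RNA, 1 control and 1 BMI1 knockdown array from each of 4 established neuroblastoma cell lines: NB-39-nu, SH-SY5Y, SK-N-BE and SK-N-DZ. Per the labels, the control cells carried an empty lentiviral vector and the knockdown cells a lentiviral vector with a short hairpin RNA against BMI1. Per the labels, RNA was taken between day 8 and day 14 after infection. The day of each sample is not given in the sources used here. No label says whether the 2 samples of a line were harvested on the same day. Replicates of a condition are therefore different cell lines, and within a line there is no replicate. The number of arrays limits the precision.

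Each array was an Affymetrix HG-U133 Plus 2.0 array, which reports a probe set as a summary of several short probes near the 3' end of a transcript. The deposited values are array intensities (signal) on a linear scale, 1 per probe set and array. The submitters' processing notes name GCOS and MAS5, the Affymetrix programs that summarise probes into a signal and scale arrays to a common mean, with no version given. The values fit that description: the mean signal after trimming 2% at each end was 500 on each array. Median signals ran from 69.9 to 79.8. The deposited table has no present or absent calls, so dim probe sets were handled by a filter on the mean. Scanner files were not used here.

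The table held 54675 probe sets. The platform annotation gave a single gene for 41097 of them and several genes for 1801, and 11777 were unnamed here. Of the single-gene probe sets, 41043 had a gene identifier in the RefSeq gene table of GRCh38.p14 and took its current symbol, and the rest kept the annotation's symbol. No coordinates are given, because the array table names no genome build. Probe sets with several genes were left unnamed, with 1 exception. The only BMI1 probe set is annotated both to BMI1 and to a read-through transcript that joins the neighbouring gene COMMD3 to BMI1. It was used as BMI1, since the design needs the targeted gene, and it cannot separate the 2 transcripts.

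Signals were converted to log2(signal + 8), where 8 is the table's median of 75.0 divided by 10 and rounded. Fold changes are on this scale, which understates the change of dim genes. Each gene was represented by its probe set with the highest mean over the 8 arrays. Of 19776 genes, the 9888 with a mean above the median were tested. A linear model with cell line as a block was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. No further normalization was applied in this fit. Cell line pairs the arrays, because the labels name the line of every array. Each knockdown array correlated best with the control array of its own line, at r of at least 0.934 across probe sets, against at most 0.886 between lines. These correlations are across probe sets, which are not independent replicates. The fit without the block was run as an alternative.

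Per-line values are log2 ratios of 1 array over 1 array and carry no test. Differences of single values between conditions were tested over the 4 lines by an exact sign-flip permutation test, two-sided, whose smallest possible p is 0.125. That design cannot reach the 0.05 threshold. Counts of genes that moved the same way in all lines were set beside the 8 distinct sign combinations of the 4 lines.

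For gene groups, 37 lists were fixed before the data were examined, and 33 had at least 5 tested members. They cover Polycomb subunits, reported BMI1 targets, p53 targets, apoptosis, DNA damage repair, cell cycle, neuroblastoma cell states, neuronal genes, stress, metabolism and markers of other cell types. Each was tested with limma's camera with its preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. Members were also adjusted over their list alone, which does not correct across the lists. Within a line, the median of a list was placed among the medians of 10000 random lists of equal size matched on mean expression in 20 bins. That percentile describes 2 arrays and is not a test of the condition.

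Genes named in the text were chosen by a rule fixed before the data were examined. The rule takes BMI1, the measured PRC1 members and reported BMI1 targets, and MYCN. It takes the 10 largest rises and 10 largest falls past the threshold, filled with genes that moved the same way in all 4 lines, ranked by the smallest of their 4 changes. It also takes up to 2 members at each end of every list, and the 3 highest and 3 lowest genes in each line. Genes that mark sex are never named. Any other gene is said to have been chosen after its values were seen.

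The alternatives planned before the data were examined were no pseudocount, a pseudocount of the table median, no filter, a stricter filter at the 75th percentile, quantile normalization, the mean of all probe sets of a gene, no cell line block, eBayes without trend, robust eBayes, array weights, and leaving out each line. Testing every probe set on its own, a 1.5-fold threshold, an estimated correlation and fry were planned for single results. An estimated correlation with each line left out was added after seeing the data. Changes of sign among values that passed in neither setting were not counted as reversals, since no direction had been called. The numbering used in leaving lines out follows the order of the samples, with 1 for NB-39-nu, 2 for SH-SY5Y, 3 for SK-N-BE and 4 for SK-N-DZ.

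The fit was checked on simulated data for the same 9888 genes and 8 arrays, with the real means, line effects and estimated spread. In 5 simulations, 200 genes were given known changes. Of genes lowered 2-fold in the mean, 71.6% were called, of those raised 2-fold 78.0%, of those lowered 4-fold 99.2% and of those raised 4-fold 98.8%. On average 9.4 unchanged genes were called per simulation. These shares hold for 200 changed genes. The adjustment is stricter where fewer genes change, so the shares do not give the power in the real data, where 1 gene was called. A neuronal list raised by 0.5 log2 was called by camera in all 5 simulations, with 0 other lists called. In these simulations genes varied independently, so they say nothing about camera when genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.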

Results

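Expression was measured on 8 arrays from 4 human neuroblastoma cell lines, each infected with a control lentivirus or with a lentivirus carrying a short hairpin RNA against BMI1. BMI1 is a core subunit of Polycomb repressive complex 1 (PRC1), which represses transcription by marking histone H2A. Neuroblastoma is a childhood tumour of the sympathetic nervous system. The series title places the work around protection of these cells from apoptosis after DNA damage, and its stated question was which genes respond to loss of BMI1. There were 4 control and 4 knockdown arrays, with 1 of each per line. RNA came from day 8 to day 14 after infection. All arrays had been scaled to a trimmed mean signal of 500. P-values of single genes below set the mean change against the spread between lines. The fit draws each gene's spread toward that of genes with similar mean signal, so an SD over lines does not give the p-value by itself. Camera p-values set the genes of a list against the other genes.

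BMI1 was lower after knockdown in all 4 lines, most in NB-39-nu and least in SH-SY5Y and SK-N-BE, which were alike. Its signal went from 7175 to 1765 in NB-39-nu, which leaves 24.6%, and from 3345 to 1318 in SK-N-DZ, which leaves 39.4%. In SH-SY5Y 65.5% was left (5169 to 3386) and in SK-N-BE 65.0% (3647 to 2371). The mean log2 fold change was -1.15 ± 0.67 (SD, n = 4 lines), with a standard error of 0.22 in the limma fit. It did not pass the threshold over all genes (limma adjusted p = 0.276). An exact two-sided sign-flip test over the lines gave p = 0.125, the smallest it allows. Among the 17 tested PRC1 members, BMI1 alone passed when adjusted over the list alone (limma adjusted p = 0.0104). The probe set also matches the read-through transcript from COMMD3. COMMD3's own probe set, looked at after its values were seen, read 4946 and 5309 in the control and knockdown arrays of NB-39-nu and 2458 and 2388 in those of SK-N-DZ.

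**Figure D1:**
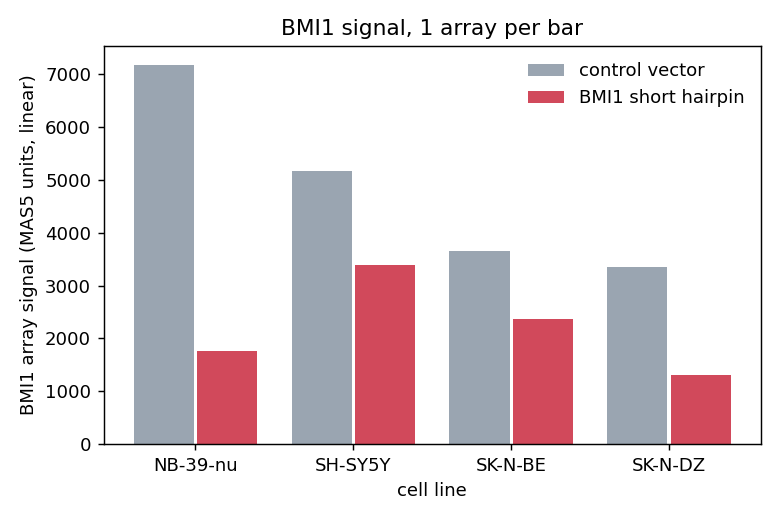
BMI1 array signal on a linear MAS5 scale (vertical axis) in each cell line (horizontal axis), with 1 array per bar, grey for the control vector and red for the BMI1 hairpin. The knockdown bar is lower in each line, with 24.6% of the control signal left in NB-39-nu and 65.5% in SH-SY5Y.

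None of the tested PRC1 subunits passed the test over all genes. CBX7, another subunit, lay under the filter and was not tested. RYBP, a subunit of the variant complexes, had a mean log2 fold change of -0.31 ± 0.15 (SD, n = 4 lines) and was lower in 4 of 4 lines. CBX6, a chromobox subunit that can bind methylated histone H3, was at -0.26 ± 0.05 and also lower in 4 of 4. The BMI1 paralogues PCGF1 and PCGF3 were at 0.28 ± 0.39 and 0.21 ± 0.09, and PCGF2, the closest paralogue, was at 0.02 ± 0.13. PCGF5 was at 0.07 and PCGF6 at 0.09. RING1, an enzymatic partner, was at 0.12 ± 0.16. PHC1, PHC2 and PHC3 were at -0.08, 0.25 and -0.12. The remaining members CBX2, YAF2, KDM2B, SCMH1 and SCML2 had means of 0.05, 0.19, 0.11, 0.06 and 0.10. As a list, PRC1 had a mean of -0.02, a median of 0.07 and a downward camera test (adjusted p = 0.889). That list includes BMI1, the hairpin's target, so its mean and direction say nothing about the other subunits. The 12 members of PRC2, the complex that methylates histone H3, had a mean of 0.07 (camera adjusted p = 0.828). JARID2 was highest there at 0.44 ± 0.24, and the methyltransferase EZH2 lowest at -0.22 ± 0.63. JARID2 was higher in 4 of 4 lines but did not pass (limma adjusted p = 0.371).

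Genes that earlier work has linked to repression by BMI1 showed no shared response. CDKN2A, which encodes the cell cycle inhibitor p16 and the p53 activator ARF, was at 0.07 ± 0.40 (SD, n = 4 lines). KIF1B and CADM1, both regarded as tumour suppressors in neuroblastoma, were at 0.10 ± 0.18 and 0.10 ± 0.21. WWOX was at 0.19 ± 0.34. CDKN1A, which encodes the cell cycle inhibitor p21, split the lines, at 1.24 in NB-39-nu, 0.53 in SK-N-BE, -1.01 in SH-SY5Y and -1.76 in SK-N-DZ, where it was dim (136 and 34.4). Of the 5 tested targets, 0 passed over all genes and 0 when adjusted over the list alone, and camera gave an adjusted p of 0.856. CDKN2B, CDH1 and HOXC13 lay under the filter and were not tested. MYCN, the oncogene amplified in many neuroblastomas, was at 0.14 ± 0.40. Its control signal was 449 in SH-SY5Y and between 43219 and 59743 in the others. Of the HOX genes, classical Polycomb targets, only HOXC4, HOXC6, HOXD8 and HOXD10 were bright enough to test. HOXD8 was at 0.33 ± 0.16 and HOXC6 at 0.28 ± 1.39, though dim in NB-39-nu (4.73 to 54.9).

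Over all genes, BLOC1S6 alone passed. It encodes pallidin, a subunit of a complex that forms lysosome-related organelles. Its mean log2 fold change was -1.25 ± 0.27 (SD, n = 4 lines; SE 0.12; limma adjusted p = 0.0298). Its signal was lower in 4 of 4 lines, for example from 9148 to 3533 in SK-N-BE. Its other probe sets were lower by means of -1.29 and -1.03, in 4 of 4 lines each. Next came SEC23A, a coat protein of vesicles leaving the endoplasmic reticulum, at -1.15 ± 0.31 (limma adjusted p = 0.0684), but its other probe set had a mean of -0.06 and was higher in 3 of 4 lines. At an unadjusted p under 0.05, limma gave 923 of 9888 genes, 492 higher and 431 lower. At p under 0.01 it gave 230, 93 higher and 137 lower. The single call was lost when SK-N-BE or SK-N-DZ was left out (0 genes each). It was also lost without the trend, with the mean of all probe sets, without the line block or with every probe set on its own (0 genes each). SEC23A joined it when NB-39-nu or SH-SY5Y was left out, for 2 genes each.

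No gene was at least 2-fold higher or lower in the same direction in all 4 lines, and 8 were at least 1.5-fold higher or lower. The 6 lower ones were BMI1, BLOC1S6, SEC23A, SGPP1, NID1 and IFITM3. The 2 higher ones were SKIDA1 and RGS2. The highest count of such genes under any other sign combination of the lines was 3. The real count includes BMI1, the hairpin's target. Each gene can be counted under only 1 sign combination, so these counts are not independent. In all, 1800 genes (18.2%) moved the same way in all 4 lines, where chance gives 12.5% for independent lines. The other sign combinations gave between 826 and 1573. With 1 line left out, 1 gene was at least 2-fold lower in the other 3 without NB-39-nu (IFITM3), and 2 without SK-N-BE (AHNAK and ROBO3). Without SH-SY5Y there were 7, of which ARFGAP3, BLOC1S6, NID1, SEC23A and SGPP1 were lower and DCX and RETREG1 higher, and without SK-N-DZ 0. AHNAK, ROBO3, DCX and RETREG1 were chosen after their values were seen.

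The genes below moved the same way in all 4 lines and were ranked by the smallest of their 4 values, and none of them passed the test over all genes. Among the genes lower in all lines, SGPP1, a phosphatase of sphingosine 1-phosphate, was at -1.40 ± 0.56 and SPTLC1, a subunit of the first enzyme of sphingolipid synthesis, at -0.75 ± 0.29. The vesicle transport genes were SEC23A and ARFGAP3 (-1.01 ± 0.36), which acts on the Golgi coat. NID1, a basement membrane protein, was at -1.27 ± 0.58 but dim in SK-N-DZ (29.6 to 1.20), and CD2AP, an adaptor of the actin cytoskeleton, at -0.61 ± 0.05. IFITM3, an interferon-induced membrane protein, was at -1.82 ± 1.00 and dim after knockdown in SH-SY5Y (43.1), SK-N-BE (15.0) and SK-N-DZ (42.5). Its probe set is of a type that can bind related transcripts. ROR1, a Wnt receptor, was at -0.70 ± 0.09, but its other probe sets had means of 0.03 and 0.33.

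Among the genes higher in all lines, SKIDA1 was at 1.02 ± 0.20 (limma adjusted p = 0.137) and RGS2, which dampens G protein signalling, at 0.87 ± 0.29. The other SKIDA1 probe set, also above the filter, had a mean of 0.32 and was lower in SK-N-BE (-0.21). ELAVL2, a neuronal RNA-binding protein, was at 0.76 ± 0.15, with 0.85 in NB-39-nu, 0.54 in SH-SY5Y, 0.84 in SK-N-BE and 0.79 in SK-N-DZ. NEFM, the medium neurofilament chain, was at 1.42 ± 1.40, led by 3.51 in NB-39-nu, where its control signal was dim (10.5 to 204). The pseudogenes ABCA11P and DPY19L2P2 were at 0.87 ± 0.35 and 0.62 ± 0.21. PDRG1 was at 0.63 ± 0.16. PIP5K1A (0.56 ± 0.07), SPN (0.76 ± 0.24) and WNK2 (0.77 ± 0.32) each had dimmer probe sets that went the other way in the mean.

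**Figure D2:**
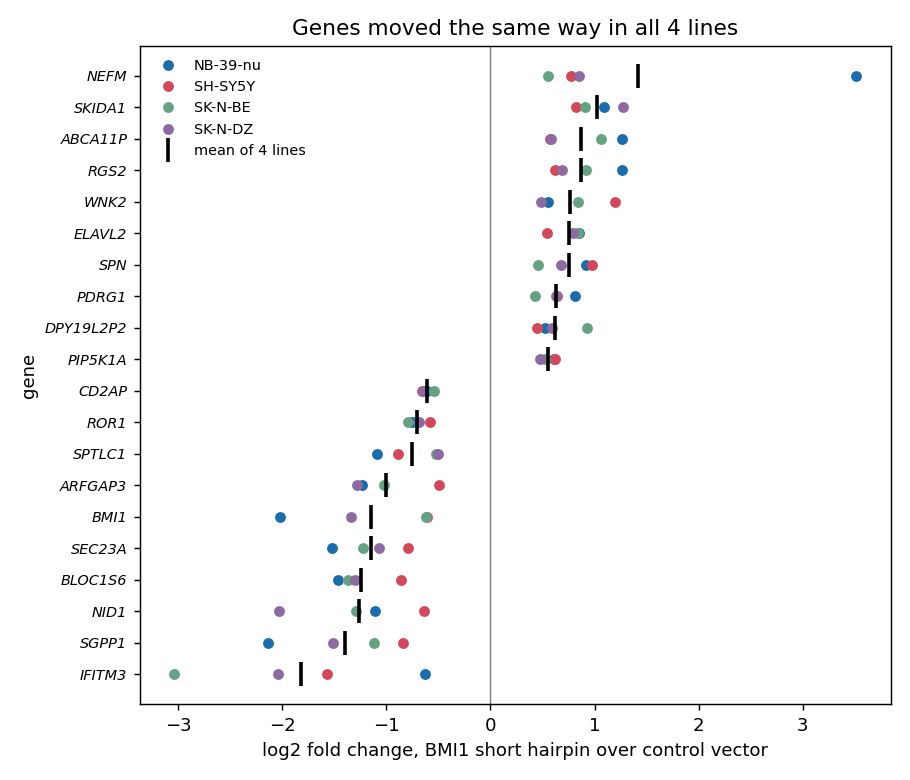
Log2 fold change of BMI1 hairpin over control vector (horizontal axis) for the 10 highest-ranked genes in each direction (vertical axis). Coloured points are the 4 lines, 1 array pair each, and black ticks their means. BLOC1S6, at a mean of -1.25, is the only one past the threshold, and NEFM has 1 point, NB-39-nu at 3.51, far from the rest.

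The question of DNA damage and cell death was followed through lists of p53 targets, apoptosis genes and repair genes. The labels used here name no DNA-damaging treatment, so a response to such treatment was not measured. None of these lists passed over the 4 lines. The 30 tested p53 targets had a mean log2 fold change of -0.04 ± 0.35 (SD over lines; camera adjusted p = 0.737), with 13 higher and 17 lower in the mean. TNFRSF10B, a death receptor, was highest at 0.38 ± 1.07, though dim in SK-N-DZ (9.26 to 55.8), and TP53INP1 lowest at -0.42 ± 0.67. The lines differed in direction. In NB-39-nu 27 of 30 were higher with a mean of 0.36, and in SH-SY5Y 2 of 30 were higher with a mean of -0.47. SK-N-BE and SK-N-DZ had means of 0.10 and -0.14. Without NB-39-nu the list passed downward with the preset correlation (mean -0.17, camera adjusted p = 3.9e-04; adjusted p = 0.827 with an estimated correlation). Estimated correlations without 1 line were added after the data were seen, and no list passed with them.

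The 23 pro-apoptotic genes had a mean of -0.03 ± 0.09 (SD, n = 4 lines; camera adjusted p = 0.828), with PMAIP1, which encodes the BCL2 family member NOXA, at -0.39 ± 1.08 (dim in SK-N-DZ) and the caspase CASP6 at -0.38 ± 0.29. The other PMAIP1 probe set, nearly as bright, had a mean of 0.23. It read -0.01 in SK-N-DZ, where the one used read -1.95, so the direction of PMAIP1 is uncertain. BCL2L11, which encodes BIM, was at 0.18 ± 0.31. The 12 anti-apoptotic genes were at -0.03 ± 0.05 (camera adjusted p = 0.856), with MCL1 at 0.27 ± 0.25, BAG1 at 0.31, BCL2L2 at -0.34 ± 0.25 and BAG3 at -0.33. Among 24 checkpoint genes, H2AX, the histone phosphorylated at DNA breaks, was at 0.53 ± 0.40, CDC25A at 0.53, and the kinase ATM at -0.40 ± 0.31. Dimmer probe sets above the filter had means of 0.08 for CDC25A and 0.0016 for ATM. The checkpoint list had a mean of 0.02, a median of -0.03 and a downward test (camera adjusted p = 0.889). Homologous recombination genes had a mean of 0.06 ± 0.22 (camera adjusted p = 0.828), led by RAD51D at 0.29 and ended by FANCG at -0.39. Without NB-39-nu that list passed upward with the preset correlation (mean 0.16, camera adjusted p = 0.00517; adjusted p = 0.827 with an estimated correlation). End joining genes had a mean of 0.11 (camera adjusted p = 0.889) and excision and mismatch repair genes one of 0.09 (camera adjusted p = 0.737), with the glycosylase OGG1 at 0.45 ± 0.41.

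Of the 33 lists, 6 passed camera with its preset correlation. None passed with an estimated correlation, where adjusted p ran from 0.879 to 0.971, and none with fry, whose lowest adjusted p was 0.274. With the control and knockdown arrays of 1 or more lines exchanged, camera called between 4 and 16 lists in the 7 other splits.

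Neuronal differentiation genes rose in this test, with a mean of 0.48 ± 0.69 (SD, n = 4 lines; camera adjusted p = 1.3e-05; adjusted p = 0.967 with an estimated correlation). Of 28 tested members, 25 were higher in the mean, 0 passed over all genes, and ELAVL2 passed when adjusted over the list alone (limma adjusted p = 0.00294). NEFM at 1.42 and SCG2, a granin of secretory granules, at 1.19 were highest. CADPS, a factor for vesicle release, was lowest at -0.38. The mean was 1.44 in NB-39-nu, 0.33 in SK-N-BE and 0.35 in SK-N-DZ, and -0.19 in SH-SY5Y. Without NB-39-nu it was 0.16 (camera adjusted p = 0.00517; adjusted p = 0.827 with an estimated correlation). Without the line block the call was lost (camera adjusted p = 0.0570).

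Ribosomal protein genes rose by a small amount, 0.13 ± 0.09 (SD, n = 4 lines; camera adjusted p = 6.6e-12; adjusted p = 0.967 with an estimated correlation), but under quantile normalization the mean was 0.02 and the call was lost (camera adjusted p = 0.780). All 41 members were higher in the mean, from RPL22 at 0.02 to RPL34 at 0.24. Histone genes, 6 for core histones and 1 for a linker histone, rose by 0.49 ± 0.61 (camera adjusted p = 0.0109; adjusted p = 0.967 with an estimated correlation). The 7 members were higher in the mean, with H2BC21 at 0.92 and H2AC6 at 0.78. Without NB-39-nu their mean was 0.20 (camera adjusted p = 0.300). Hypoxia and glycolysis genes rose by 0.23 ± 0.49 (camera adjusted p = 0.0024; adjusted p = 0.967 with an estimated correlation), but without NB-39-nu their mean was -0.0046 and the call was lost (camera adjusted p = 0.891). Array weights also ended the calls of histones and of hypoxia and glycolysis (camera adjusted p = 0.0938 and 0.307).

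Antioxidant response genes, mostly targets of the transcription factor NRF2, fell by a mean of -0.14 ± 0.09 (SD, n = 4 lines; camera adjusted p = 0.0024; adjusted p = 0.879 with an estimated correlation). The mean was negative in 4 of 4 lines. Of 24 members, 17 were lower in the mean, and NQO1, ME1 and GCLM passed when adjusted over the list alone (limma adjusted p = 0.031 each). NQO1, a quinone reductase, was at -0.67 ± 0.50, the heme oxygenase HMOX1 at -0.62 ± 0.64, ME1 at -0.55 and GCLM, which serves glutathione synthesis, at -0.46. ME1 and GCLM were chosen after their values were seen. The highest members were SOD2 at 0.14 and GPX4 at 0.11.

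Interferon response genes fell by a mean of -0.21 ± 0.19 (SD, n = 4 lines; camera adjusted p = 0.0288; adjusted p = 0.967 with an estimated correlation). IFITM3 and PSMB9, an immunoproteasome subunit, passed when adjusted over the list alone (limma adjusted p = 0.0136 and 0.0362). PSMB9 was at -1.04 ± 0.64 and dim in SH-SY5Y and SK-N-DZ. The median of the 19 members was -0.04, with OAS3 at 0.27 and IRF9 at 0.25, so a few members carried the mean. The call was lost without SK-N-BE (mean -0.13, camera adjusted p = 0.187) with no filter or a stricter filter on dim genes, and without the line block.

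NB-39-nu had the smallest share of its control BMI1 signal left and the most 2-fold genes, 469 higher and 192 lower. SH-SY5Y had 76 and 86, SK-N-BE 101 and 47, and SK-N-DZ 109 and 115. These counts come from 1 array pair each and have no replicate check. The 3 highest and 3 lowest genes of each line, named below, had at least 1 of their 2 signals under the table median, so the size of these folds is uncertain. Fold changes agreed little between lines. The mean Pearson r across genes over the 6 pairs of lines was 0.090 ± 0.094 (SD over pairs), from -0.053 for NB-39-nu with SH-SY5Y to 0.225 for NB-39-nu with SK-N-BE. Genes are not independent replicates in these correlations.

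In NB-39-nu, 25 of 28 neuronal genes were higher after knockdown and 15 were at least 2-fold higher. SCG2 was higher by 4.42 on the log2 scale (203 to 4505) and NEFM by 3.51. The highest genes of that line were ADGRB3-DT at 5.00, the sodium channel subunit SCN3B at 4.63 and the neuropeptide gene NTS at 4.42. The lowest were SLC7A11, the cystine transporter, at -3.34, the potassium channel KCNQ5 at -2.80 and RASL10B at -2.66. Dimmer probe sets of KCNQ5 and RASL10B, under the filter, read 1.11 and 1.29 in NB-39-nu. All 26 hypoxia and glycolysis genes were higher there, with a mean of 0.94, led by ADM at 3.43 and ANKRD37 at 2.88. Mitosis genes were lower in 47 of 47 cases, with 0 higher, at a mean of -0.55. DNA replication genes had a mean of -0.54 and the inhibitor gene CDKN2D was at 1.81. Of the markers of endothelium and fibroblasts, 4 were bright enough to measure. LUM was at 1.36 (5522 to 14204), ACTA2 at 1.15, PDGFRA at 1.72 and COL1A1 at 0.57 in the same array pair. Dimmer probe sets of ACTA2 and COL1A1, under the filter, included falls in that pair. In the 3 other lines the mean of the 4 markers was -0.12 in SH-SY5Y, -0.67 in SK-N-BE and -0.06 in SK-N-DZ. The blood cell markers ITGB2 and CORO1A were at -0.99 and 0.03 in NB-39-nu. None of the Schwann-type markers was bright enough to test.

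In SH-SY5Y the cell cycle lists lay on the other side. Mitosis genes had a mean of 0.51, with 45 of 47 higher, and DNA replication genes one of 0.53, with 43 of 45 higher. RRM2, a subunit of ribonucleotide reductase, was at 1.34 and CDC25C, which drives entry into mitosis, at 1.03. Over the 4 lines these lists had means of 0.01 and -0.01 (camera adjusted p = 0.845 and 0.828). The mean of the mitosis list opposes its downward camera direction. Without NB-39-nu, mitosis genes passed upward with the preset correlation (mean 0.20, camera adjusted p = 1.0e-06; adjusted p = 0.831 with an estimated correlation). Without SH-SY5Y they passed downward (mean -0.15, camera adjusted p = 1.1e-05; adjusted p = 0.959 with an estimated correlation). DNA replication genes likewise passed upward without NB-39-nu (mean 0.16, camera adjusted p = 3.9e-04; adjusted p = 0.888 with an estimated correlation). They passed downward without SH-SY5Y (mean -0.19, camera adjusted p = 7.4e-06; adjusted p = 0.959 with an estimated correlation). The highest genes of SH-SY5Y were the complement regulator CD55 at 2.32, SLC12A7 at 2.21 and the repressor BCL6 at 2.04. The other CD55 probe sets, above the filter, read -0.64 and 0.17 in that line. The lowest were SLC25A43 at -3.16, ATP9A at -2.76 and EFHD1 at -2.66.

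In SK-N-BE, the phosphatase PTPRK was at 3.54, LZTS3 at 3.18 and ARID3B at 2.88, and the lowest were IFITM3 at -3.04, ATP2A1-AS1 at -2.76 and EPB41L4A at -2.55. Genes of the unfolded protein and amino acid stress list had a mean of 0.35 there and -0.39 in NB-39-nu. CHAC1, a target of the stress factor ATF4, was at 1.95 in SK-N-BE, 1.58 in SK-N-DZ and -2.45 in NB-39-nu, and dim in 1 array of each of the last 2 lines (48.2 and 38.1). In SK-N-DZ, PDE3A was at 2.63, LGALS3 and MBOAT1 at 2.60 each, and the lowest were EFNA1 at -3.37, PCSK7 at -2.94 and the transcription factor ETS1 at -2.83. VIM, the intermediate filament of mesenchymal cells, was dim in SK-N-DZ and at -2.45 there (112 to 14.0).

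**Figure D3:**
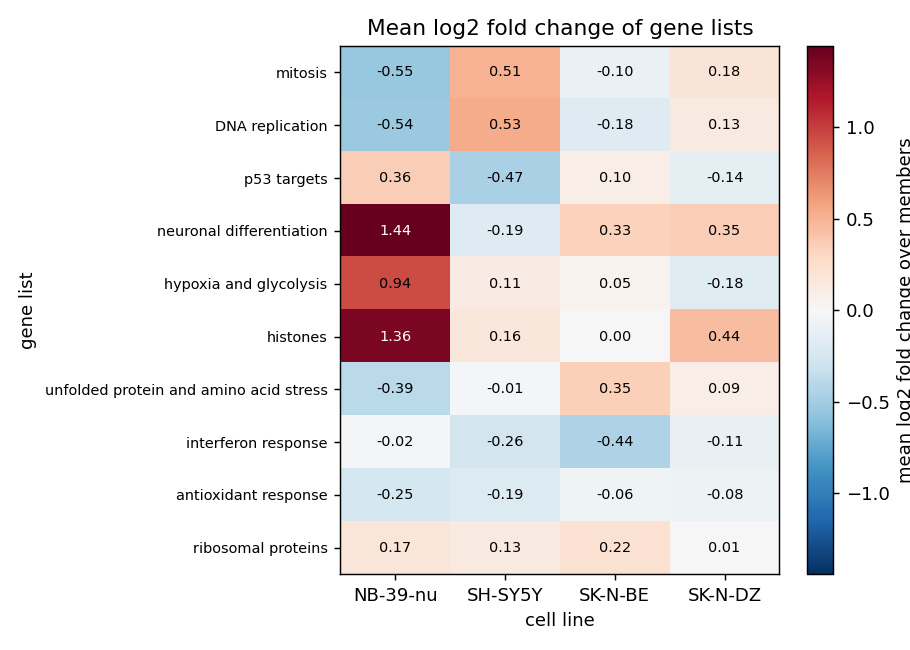
Mean log2 fold change over the members of 10 gene lists (vertical axis) in each cell line (horizontal axis), printed in each cell and coloured from blue (lower after knockdown) to red (higher). Each column is 1 array pair. Mitosis genes are at -0.55 in NB-39-nu and 0.51 in SH-SY5Y, and neuronal genes reach 1.44 in NB-39-nu.

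The remaining lists did not pass over the 4 lines. Adrenergic identity genes, which mark the sympathetic type of neuroblastoma cell, had a mean of -0.01 (camera adjusted p = 0.889), with CHGB at 0.63 ± 0.52 and CYB561 at -0.52 ± 0.78. Other CYB561 probe sets of similar brightness had means of 0.37, -0.25 and -0.03. Mesenchymal identity genes had a mean of 0.05, a median of -0.07 and an upward test (camera adjusted p = 0.934). Neural crest genes were at -0.04 (camera adjusted p = 0.889), with ID3 at 0.69 ± 0.68 and ETS1 at -0.98 ± 1.26. The cyclin-dependent kinase inhibitor and RB list was at 0.04 (camera adjusted p = 0.889). There RBL2, a relative of RB, was at -0.56 ± 0.25 and passed when adjusted over the list alone (limma adjusted p = 0.029). Cholesterol synthesis genes were at -0.08 (camera adjusted p = 0.173), with SC5D at -0.61 and LSS at -0.40, and heat shock genes at -0.10 (camera adjusted p = 0.179). With the preset correlation, cholesterol synthesis passed without SH-SY5Y (mean -0.15, camera adjusted p = 0.00738; adjusted p = 0.959 with an estimated correlation). Heat shock passed without SK-N-DZ (mean -0.15, camera adjusted p = 0.0339; adjusted p = 0.931 with an estimated correlation).

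RNA quality was read from the 3' to 5' signal ratios of control probe sets. The ACTB ratio ran from 3.81 to 6.01 and its mean log2 change after knockdown was -0.01 ± 0.24 (SD, n = 4 lines; exact sign-flip p = 1). The GAPDH ratio ran from 0.975 to 1.12 (exact sign-flip p = 0.75). The ACTB change was -0.32 in NB-39-nu, 0.15 in SH-SY5Y, 0.22 in SK-N-BE and -0.08 in SK-N-DZ.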

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

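The numbered patterns below were picked from the results, so the tests of their explanations were chosen with those results known. These tests were chosen before their own values were seen, with exceptions. Exceptions were RNA quality against the mitosis list, other probe sets read gene by gene and the shared hairpin. Over 231 quantities with 1 value per line, 13 had 1 line far from the other 3, where chance alone gives about 5% of independent quantities. The number is near that share. These quantities share arrays and some share genes, so their number cannot show whether a given one arose by chance. Opposite extremes of gene lists between lines were not tested, since each line has 1 array per condition.

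NB-39-nu stood apart in the number of 2-fold genes, 661 against 148 to 224 in the others, and of 2-fold higher genes, 469 against 76 to 109. The same line stood apart for NEFM (3.51), ADM (3.43), ANKRD37 (2.88), TIMP1 (0.16), TFAP2B (-2.35) and RASL10B (-2.66). TFAP2B was dim in that line, at signals of 41.8 and 1.75, and NEFM (10.5) and RASL10B (45.3) were dim in 1 of its arrays. The other TFAP2B probe sets went the other way in NB-39-nu, at 0.70 and 2.25. So did the other RASL10B probe set, dimmer and under the filter, at 1.29. SH-SY5Y stood apart for SLC25A43 (-3.16), SK-N-BE for SOD2 (-0.71), and SK-N-DZ for VIM (-2.45), COX7C (0.20) and MBOAT1 (2.60), of which SLC25A43 and MBOAT1 were dim. VIM was dim in its knockdown array (14.0). Genes named for being extreme in 1 line meet this criterion more easily.

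The first pattern was the higher level of neuronal genes in the NB-39-nu knockdown array, with a list mean of 1.44. RNA of another line in that array would bring that line's abundant transcripts. Genes bright in SH-SY5Y, SK-N-BE or SK-N-DZ (at least 2000) and dim in the NB-39-nu control (at most 100) implied median shares of at most 0.390%, while the neuronal genes at least 2-fold higher needed median shares from 10.6% to 100.4%. Scaling between arrays is argued against by a list mean of 1.39 under quantile normalization, with the list median above those of all random lists. What stays open is the depth of the knockdown, which was greatest in this line as a share of control. The unknown harvest days, selection of surviving cells and cells from outside the series stay open too. RNA quality was not tested for this pattern and stays open. The ACTB ratio change of NB-39-nu, -0.32, was the largest in size of the 4 lines. So do an action of the hairpin on other transcripts and chance between 2 single arrays. The 4 endothelial and fibroblast markers were higher in the same pair by their brightest probe sets. Dimmer ones under the filter were split, for example -2.22 for COL1A1 and -2.97 for ACTA2 but 1.36 for LUM. An effect of BMI1 loss on neuronal genes may be 1 of these explanations and was not tested apart from them.

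The second pattern was the opposite change of cell cycle genes, with the mitosis list 1.06 higher in SH-SY5Y than in NB-39-nu in log2 fold change and the DNA replication list 1.07. Scaling between arrays is argued against by a mitosis difference of 1.04 under quantile normalization. RNA quality stays open, since the ACTB ratio change was also higher in SH-SY5Y than in NB-39-nu. It was higher in SK-N-BE than in SK-N-DZ as well, where the mitosis list differed by -0.28, but 1 pair of lines beside an SD of 0.45 over the 4 lines decides nothing. Growth state and day at harvest could differ between the arrays of a line and stay open. A line-specific effect of BMI1 loss and an action of the hairpin on other transcripts stay open as well.

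The third pattern was the 6 genes at least 1.5-fold lower in all 4 lines, with the target BMI1 among them, against 2 higher. A faulty probe set is argued against for BLOC1S6 and SGPP1, whose 3 other probe sets, all above the filter, were each lower in 4 of 4 lines. Over BLOC1S6, SGPP1, NID1 and SEC23A, 83.3% of the 6 other probe sets were lower in the mean, but that share let some genes stand for others and counted dim probe sets of NID1. NID1 and SEC23A stay open, with 0 other probe sets above the filter that were lower in 4 of 4 lines, as do BMI1 and IFITM3, which have no other. All 4 lines received the same hairpin and no second hairpin or seed search was analysed, so a direct action of the hairpin on other transcripts cannot be told apart from an effect of BMI1 loss for the 5 genes other than BMI1.

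Chance was examined by exchanging arrays between the conditions. Of the 8 splits of the arrays that part all 4 lines' pairs, the real split called 1 gene and the highest of the others 0, so 1 split reached the real count. Among the 24 splits that part the pairs of only some lines, the highest count was 1. For gene lists, the real split called 6 and the highest of the others 16, and 6 of the 8 splits called at least as many as the real one. With 8 splits a share under 0.05 cannot be reached.

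Other gene lists lay at opposite extremes of the random lists in a pair of lines. The p53 targets differed by 0.82 between NB-39-nu and SH-SY5Y, checkpoint genes by 0.50, homologous recombination genes by 0.54, ribosome biogenesis genes by 0.48 and extracellular matrix genes by 0.54. Between NB-39-nu and SK-N-DZ, adrenergic identity genes differed by 0.45 and neural crest genes by 0.80. The unfolded protein and amino acid stress list differed by 0.74 between SK-N-BE and NB-39-nu.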

How the results depend on the processing

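All alternatives here were chosen before the data were examined, except an estimated correlation with 1 line left out, which was chosen after seeing the data. The count of genes changed by BMI1 knockdown was 1 and moved to 0 with every probe set on its own, the mean of all probe sets, no replicate block and eBayes without trend. It moved to 2 with a pseudocount of the table median, no filter, a stricter filter, quantile normalization, robust eBayes and array weights, and ranged from 0 to 2 without 1 line. BLOC1S6 was among the calls wherever any gene was called, and SEC23A was the other. The BMI1 fold change kept its direction in every setting, from -1.33 to -0.86, and did not pass in any (limma adjusted p 0.135 to 1.000). Genes at least 2-fold in every line went from 0 to 8 at 1.5-fold and to 21 with no filter, which adds dim genes, and ranged from 0 to 7 without 1 line. The mean correlation between lines, 0.090, was 0.011 with no filter, 0.040 with the mean of all probe sets and 0.166 with a stricter filter, and ranged from 0.060 to 0.151 without 1 line.

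Counts of 2-fold genes within a line depended on the floor. For NB-39-nu, SH-SY5Y, SK-N-BE and SK-N-DZ they were 425, 48, 43 and 59 with a pseudocount of the table median. They were 4091, 3475, 2857 and 3475 with no filter, and 146, 19, 13 and 35 with a stricter filter. With the mean of all probe sets they were 314, 229 and 350 in the last 3 lines.

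The number of gene lists past the threshold was 6 and fell to 0 with an estimated correlation, also without any 1 line, or with fry. It ranged from 5 to 10 without 1 line. Without NB-39-nu, DNA replication reversed to 0.16 and mitosis passed upward against its downward test over all lines, while the mean of hypoxia and glycolysis went to -0.0046 and its call was lost. Without SH-SY5Y, the mean of mitosis changed sign to -0.15, with the test still downward. Over all settings without 1 line, DNA replication ranged from -0.19 to 0.16, mitosis from -0.15 to 0.20, and hypoxia and glycolysis from -0.0046 to 0.37. The ACTB ratio change ranged from -0.08 to 0.10 without 1 line. Of 192 named genes other than BMI1, only BLOC1S6 and SEC23A crossed the threshold in at least 1 setting, and 12 of 33 lists did, without counting the estimated correlation and fry. The cause of these moves was not tested, except that filters change the genes tested. Without detection calls, signal over background could not be set per probe set, so dim genes limit all fold changes.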

Other observations

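Of the tests in this part, only the estimated correlation without SH-SY5Y was chosen after the results were seen. Genes of the secretory and inflammatory list had means above 0 in 4 of 4 lines, from 0.03 in SK-N-BE to 0.26 in NB-39-nu, with 13 members tested (camera adjusted p = 0.828). In SK-N-DZ, however, the median was -0.21 and 5 of 13 were higher, so a few members carried the mean there. CCL2, a chemokine, was higher in SH-SY5Y, where it was dim (4.94 to 45.1), and at 1.05 in NB-39-nu, but at -0.30 in SK-N-BE and -0.42 in SK-N-DZ, where it was also dim. TNFAIP3, a brake on NF-kB signalling, was at 1.92 in SK-N-DZ, with a dim control signal (22.1 to 106).

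Among oxidative phosphorylation genes the list mean was 0.01 ± 0.05 (SD, n = 4 lines), but COX7C, a subunit of cytochrome oxidase, was at 0.47 ± 0.18 and passed when adjusted over the list alone (limma adjusted p = 0.0141). SDHD, a subunit of succinate dehydrogenase, was at -0.28 ± 0.07 and lower in 4 of 4 lines (limma adjusted p over all genes 0.425). Among genes of the MYC network, ODC1, a polyamine enzyme and MYC target, was at -0.36 ± 0.30 and lower in 4 of 4 lines. MXD3 was at -2.39 in NB-39-nu, dim after knockdown (343 to 58.8), and 0.68 in SH-SY5Y. That list had a mean of 3.8e-04 and a downward test (camera adjusted p = 0.889). Ribosome biogenesis genes had a mean of -0.02, with NOP2 lower in 4 of 4 lines at -0.33 ± 0.19. Without SH-SY5Y that list passed downward with the preset correlation (mean -0.10, camera adjusted p = 0.0110; adjusted p = 0.959 with an estimated correlation).

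Lysosome and autophagy genes had a mean of 0.04, with LAMP1, a lysosomal membrane protein, at 0.34 ± 0.16 and higher in 4 of 4 lines. SQSTM1, an autophagy receptor and NRF2 target, was at -0.33 ± 0.29 and lower in 4 of 4 lines, as was NQO1. Extracellular matrix genes had a mean of 0.04, a median of -0.07 and a downward test, with LOX at 2.06 in NB-39-nu and 1.06 in SH-SY5Y. Wnt pathway genes had a mean of 0.08 and immediate early genes one of -0.02. None of these lists passed camera over the 4 lines, and none of these genes passed over all genes in limma.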
